A study of Homo sapiens with 2 samples.

How the data were processed

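Gene expression was measured in THP-1, an established human monocytic leukaemia cell line, and in an azacytidine-resistant clone derived from it, named TAR. Azacytidine is a cytidine analogue that is built into RNA and DNA and traps DNA methyltransferases. Per the labels' protocols, THP-1 cells were exposed to azacytidine at rising concentrations, plated in methylcellulose with the drug and cloned from single colonies, and the clone with the highest IC50 was kept. Total RNA was extracted with acid guanidinium thiocyanate, phenol and chloroform, and antisense RNA carrying Cy5 was synthesised from it, per the labels' protocols. Each sample was hybridised to 1 single-colour CodeLink Human Whole Genome Bioarray, per the series title. The labels assign 1 array to the THP-1 control and 1 array to TAR.

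The deposited table gives 1 linear spot intensity per probe and array for 54359 probes, numbered from 1 to 54359 without gaps or repeats. The scanner software, background correction and normalization are not given in the sources used here. The deposited intensities had already been brought to a common distribution, judged from the values alone. Both columns have a median of 26.04, a 75th percentile of 99.01 and a highest value of 25250. After sorting, 69.4% of the values were exactly equal between the columns, to every decimal in the file, and the largest gap was 0.433 intensity units. Such matching of distributions removes any difference in total signal between the cell lines and makes every difference relative to the array as a whole. The lowest value, 0.001, was shared by 1566 probes on the control array and 1261 on the TAR array and was treated as a floor set by the authors' processing. Detection calls, background signals and control spots are not marked in the table used here.

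Differences were computed as log2 of the TAR intensity minus log2 of the control intensity. The medians of both arrays coincided, so the deposited normalization was kept, following a rule set before the data were examined. A probe was counted above the dim range when its mean log2 intensity over both arrays was at or above the median of all probes, which corresponds to a geometric mean intensity of 23.8. This left 27180 probes. Probes differing by at least 1 on the log2 scale (2-fold) were counted in each direction. With 1 array per cell line there is no estimate of the variation between cultures, labellings or hybridisations. No test between the cell lines was therefore computed, and the words higher and lower refer to these arrays only. The permutation p and the bootstrap interval of the closing section concern the order of the rows within these arrays. As a description of the scatter, a robust SD (the median absolute deviation scaled to the SD of a normal distribution) of the difference was taken over probes of like brightness. It mixes measurement noise with true differences. Where one array's intensity lay below that array's median, the fold was also computed against that median and is given as a lower bound.

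The row numbers were not paired with gene names in the sources used here, and none of the 54359 row numbers matched a gene symbol or identifier of the reference gene table. The 33 gene lists fixed before the data were examined, their comparison with random lists, the counts per gene and the spread between probes of a gene were therefore not computed. The rule for named genes (the largest differences in each direction above the dim range) was applied to probes and limited to 2 probes per direction.

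The alternatives listed before the data were examined were subtraction of each array's median, quantile normalization, removal of a loess trend of the difference on the mean level (span 0.3), no filter on dim probes, a filter at the 75th percentile, floors at each array's median or 25th percentile, and limits of 1.5-fold or of 1.5 on the log2 scale. Alternatives chosen after seeing the data were the floor at the array median with no filter on dim probes, removal of a running median of the difference along row number (3000 or 1000 rows, over probes above the dim range) and omission of the last segment or the last 2 segments when the rows are divided in order into 10 segments of equal size. The running median was tested on simulated data in which 200 of the 27180 probes were changed by 2 on the log2 scale. The observed drift, as given by the same running median over 3000 rows, was added, with normal scatter of the observed size. The running median recovered the drift to within 0.0416 on the log2 scale, and 97% of the raised and 98% of the lowered probes passed the 2-fold limit afterwards. Since the added drift had already been smoothed by the same step, its recovery was largely fixed in advance and does not cover shorter or sharper drifts. In the same simulation 647 unchanged probes passed the limit upwards and 508 downwards from drift and scatter before the drift was removed, and 427 did so upwards and 453 downwards from scatter alone afterwards. The scatter was sized on the observed differences and includes any true ones. These numbers therefore partly rebuild the observed counts and are not counts of false passes. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.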

Results

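The transcriptome of the azacytidine-resistant clone TAR was compared with that of its parental line THP-1 to ask which transcripts differ between resistant and control leukaemia cells. The data comprised 2 single-colour arrays, 1 for each cell line, with 54359 probes. The median intensity was 26.04 units and the mean intensity 177.9 units on each array. The floor value of 0.001 was recorded for 2.88% of the probes in the control and for 2.32% in TAR, and 296 probes were at the floor on both arrays. The number of arrays limits the precision, and no difference given here has a replicate check. Resistance, drug exposure, cloning from a single colony and the array itself all separate TAR from the control and cannot be told apart here. Probes are given by their row number because gene names were not paired with them in the sources used here.

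The intensities of the resistant and the parental cells were correlated across probes. Over the 51828 probes above the floor on both arrays, log2 intensities had a Pearson correlation of 0.88 and a Spearman correlation of 0.867 across probes, which are not independent replicates. Over the 27180 probes above the dim range these values were 0.949 and 0.936. Such correlations depend on the wide range of intensity between probes. No replicate or unrelated sample was available to judge how similar the profiles are. The median difference of those 27180 probes was -0.03 on the log2 scale and the robust SD was 0.41. The scatter depended on brightness. The robust SD was 0.81 in the dimmest 10% of these probes, with a mean level of 27.2 units, and 0.32 in the brightest 10%, with a mean level of 1571 units.

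In TAR, 1043 of the 27180 probes were at least 2-fold higher than in the THP-1 control and 745 were at least 2-fold lower. This direction turned when the end of the table was left out, with 695 higher and 737 lower probes without the last 10% of the rows and 554 higher and 705 lower without the last 20%. The dimmest 10% contributed 355 of the higher and 292 of the lower probes, where the 2-fold limit lies close to the robust SD. The brightest 10% held 37 higher and 18 lower probes. In the simulation with drift and scatter taken from these arrays, 647 unchanged probes passed the limit upwards and 508 downwards. That scatter includes any true differences, so these are not counts of false passes. Given the drift, the wide scatter of dim probes and the lack of replicates, the 2-fold counts cannot be read as numbers of changed transcripts.

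**Figure D1:**
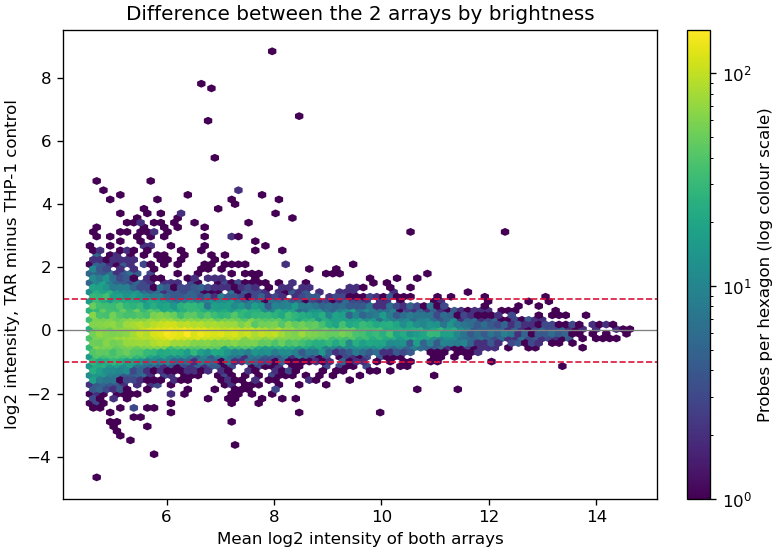
Each hexagon counts probes (log colour scale) by the mean log2 intensity of both arrays (x axis) and the log2 intensity of TAR minus the THP-1 control (y axis) for the 27180 probes above the dim range; dashed lines mark 2-fold. The cloud narrows from a robust SD of 0.81 at the dim end to 0.32 at the bright end, and the probes farthest from 0 lie above it.

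Above the dim range, large differences were mostly in the direction of higher signal in the resistant clone. At least 4-fold differences were found for 159 higher and 53 lower probes, and at least 8-fold differences for 56 higher and 7 lower probes. At least 16-fold differences were found for 19 higher probes and 1 lower probe. The higher probes made up 58.3% of the 2-fold class over all rows and 44.0% without the last 20% of the rows, and in the 8-fold class these shares were 88.9% and 87.8%. Over all 54359 probes, with dim and floor values included as deposited, the 8-fold class was nearly balanced, with 1860 higher and 1781 lower probes. When values below the array median were set to it and no probe was left out, an alternative chosen after seeing the data, 31 probes were at least 8-fold higher and 4 were lower. Over all probes, 55 lay below the array median (26.04 units) in the control and at or above the 75th percentile (99.01 units) in TAR, and 16 probes lay below the median in TAR and at or above the 75th percentile in the control.

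Among probes above the dim range, probe 40118 had the largest difference, with an intensity of 11.2 in the THP-1 control and 5130 in TAR, a difference of 8.84 on the log2 scale. Its control value lay below the array median, so the signal was at least 197-fold higher in TAR. The second largest deposited log2 difference was that of probe 52351, with an intensity of 6.93 in the control and 1468 in TAR (log2 difference 7.73, at least 56.4-fold higher as deposited and at least 37.5-fold with the drift along row number removed). Ranked by lower bound, probe 40118 stayed in place 1 and probe 52351 moved to place 4. In the other direction, probe 45155 had the largest deposited log2 difference above the dim range, with 129.8 units in the control and 5.17 units in TAR. It was lower in TAR by a log2 difference of -4.65, or at least 4.99-fold against the array median. Probe 39917 had 205.2 units in the control and 13.6 units in TAR (log2 difference -3.92, at least 7.88-fold lower), and by lower bound it ranked in place 2 and probe 45155 in place 10 of the lower probes above the dim range. The highest lower bound in this direction over all probes belonged to a probe that the filter on mean level leaves out, with 486.5 units in the control and the floor value in TAR, at least 18.7-fold lower. Without detection calls it is not known whether this floor value was a valid measurement, and the bound depends on it.

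The 2-fold counts were not spread evenly over the table, which was divided by row number into 10 segments of equal size. In segment 10 (rows 48925 to 54359), 348 probes were at least 2-fold higher in TAR and 8 were lower. In segment 9 the counts were 141 higher and 32 lower. Over segments 1 to 8, 554 probes were higher and 705 were lower, and the median difference of these segments was -0.09 on the log2 scale. The median difference was -0.14 in segment 5, 0.23 in segment 9 and 0.54 in segment 10 on the log2 scale. After a running median over 3000 rows was removed, a step chosen after seeing the data, 809 probes were higher and 648 were lower, and segment 10 held 67 higher and 58 lower probes. Segments 1 to 8 then held 655 higher and 539 lower probes, and higher probes outnumbered lower ones in each of the 10 segments.

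**Figure D2:**
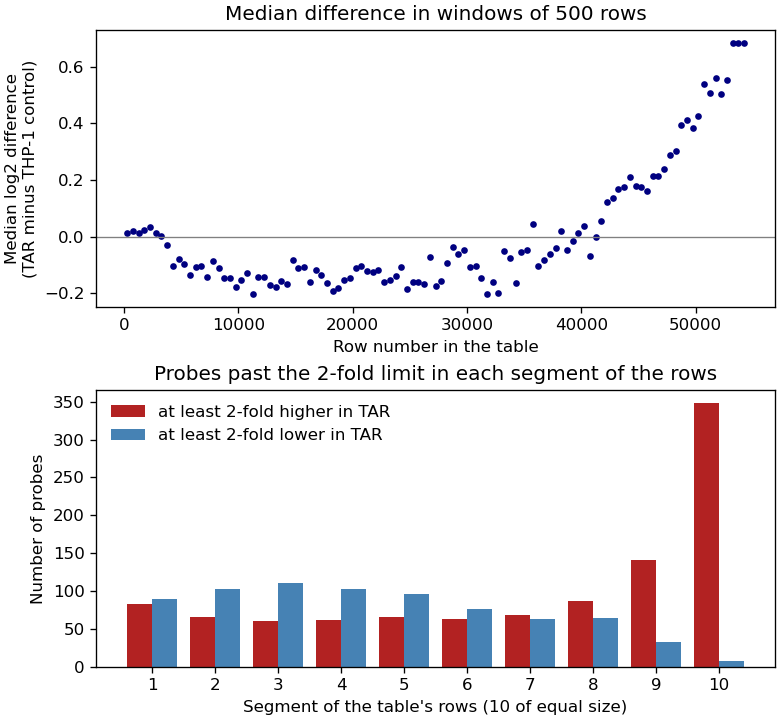
The upper panel plots the median log2 difference (TAR minus THP-1 control) of probes above the dim range in windows of 500 rows against row number, and the lower panel counts the probes at least 2-fold higher (red) or lower (blue) in each of the 10 segments of rows. The window medians lie mostly below 0 up to about row 40000 and reach 0.68 to 0.69 in the last 3 windows, and segment 10 holds 348 higher and 8 lower probes.

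The direction of the larger differences was less affected by the part of the table. In segments 1 to 8, 119 probes were at least 4-fold higher and 50 were lower, and 43 were at least 8-fold higher and 6 were lower. With the running median removed, 146 probes were at least 4-fold higher and 52 lower, and 52 were at least 8-fold higher and 6 lower. Of the probes that were below the median in one array and at or above the 75th percentile in the other, segments 1 to 8 held 45 with the higher signal in TAR and 14 with the higher signal in the control. Probe 52351 lies in segment 10, and its log2 difference was 7.14 with the running median removed. Probe 40118 and probe 39917 lie in segment 8 and had log2 differences of 8.85 and -3.91 after this step. Probe 45155 lies in segment 9 and had a log2 difference of -4.84.

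**Figure D3:**
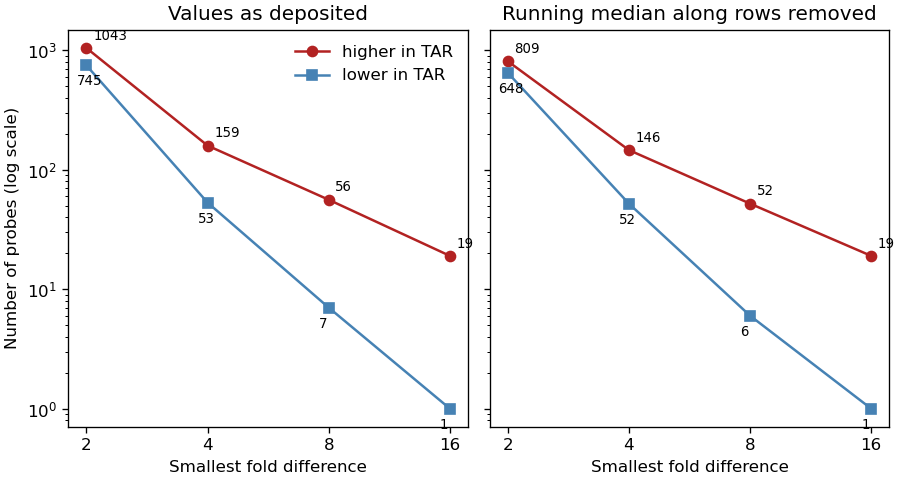
Points give the number of probes (log scale) that differ by at least the fold on the x axis, higher (red circles) or lower (blue squares) in TAR, for the values as deposited (left) and with the running median along row number removed (right). At 8-fold the counts were 56 higher and 7 lower as deposited, and 52 higher and 6 lower with the running median removed.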

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

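The balance of higher and lower probes at the 2-fold limit moved with the drift along row number, and the choices along row number were made after seeing the data. Without segment 10 of the 10 segments of rows 695 probes were higher and 737 lower, and without segments 9 and 10 there were 554 higher and 705 lower. The share of higher probes was then 48.5% and 44.0%, against 58.3% over all rows, with medians of -0.07 and -0.09 on the log2 scale in the rows kept. Removing a running median gave 809 higher and 648 lower probes over 3000 rows (55.5% higher) and 804 and 649 over 1000 rows, and after the former higher probes outnumbered lower ones in 10 of 10 segments. Without a filter on dim probes the counts were 7214 higher and 7000 lower, and with the filter at the 75th percentile 250 and 147. Limits of 1.5 on the log2 scale and of 1.5-fold gave 341 and 3008 higher and 194 and 2580 lower probes. A floor at the array median left 700 higher and 435 lower probes, or 738 and 455 over all probes with no dim filter, a combination chosen after seeing the data. The loess gave 1082 and 700. Subtracting the array medians, repeating the quantile normalization and the floor at the 25th percentile left both counts as they were. The first of these changes no value and the second almost none, since the arrays already shared a distribution. The floor at the 25th percentile could not move the counts either. A probe above the dim range with 1 value below this floor still differs by more than 2-fold after it. None of these settings is evidence of stability. The 8-fold class had more higher than lower probes under each alternative run for it (all but the 2 other limits), but with neither filter nor floor the counts were nearly balanced, 1860 against 1781. That balance depends strongly on probes at the floor value. The 8-fold counts were 20 against 1 with the strict filter, 30 against 1 with the floor at the array median, and 31 against 4 with that floor and no filter. No named probe changed sign, and the largest shift was for probe 45155 under the floor at the array median, to -2.32 on the log2 scale. The alternatives for counts per gene, gene lists and named genes were not run, because no gene names were paired with the probes. Most probes past the limit without a filter were dim.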

Other observations

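The test of the rows next to the most raised probes was set down before its result was seen, and all other tests here were chosen after the patterns had been noticed.

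The last rows of the table held an excess of probes with higher signal in TAR. Nearly the whole distribution was displaced there, since 88.7% of the probes above the dim range in segment 10 of the 10 segments of rows had a positive difference and their lower quartile was 0.26 on the log2 scale. The median intensity of all probes in a segment fell from segment 1 to 10, from 36.4 to 17.6 units in the control and from 34.5 to 21.3 in TAR. In segment 8 it was 22.3 on both arrays, so the later fall was larger in the control. Whether this follows slide position or the genes in those rows was not tested. A trend with brightness is argued against, because the gap between the median of segment 10 and that of segments 1 to 8 was 0.631 before and 0.633 after the loess on mean level, and it ranged from 0.617 to 0.675 over 4 classes of brightness. Only periods of 100 to 120 rows were searched in the residual difference. The strongest was a wave of 110.5 rows with an amplitude of 0.026 on the log2 scale and a power of 33.8 times the average. This power exceeded the highest of 1000 permutations of the residuals (11.2, one-sided permutation p = 0.001, the smallest they can give). The permutations remove all order along the rows, so any correlation between nearby rows could exceed them. The number of spots per row of the slide is not given in the sources used here. Such a wave would arise if row number followed the rows of spots, but it does not show that it did. If row number follows slide position, a gradient across 1 or both arrays is a candidate explanation for the 348 higher probes in segment 10. A true change shared by the genes in those rows stays open, as it was not tested.

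A different pattern was the excess of higher over lower probes among the differences of at least 8-fold above the dim range, 56 against 7. Over all probes as deposited, with values at or near the floor included, higher probes made up 51.1% of this class (1860 against 1781). That share depends strongly on how many probes lay at the floor on either array. Above the dim range the share was 88.9%, and those 56 and 7 probes are part of the larger counts. The counts were 31 against 4 over all probes once values below the array median were set to it. Among probes at the floor in one array and bright in the other there was no excess, 3 in TAR against 4 in the control. The drift along row number does not account for the excess above the dim range, because 52 against 6 were left after the running median was removed, and segments 1 to 8 alone held 43 against 6. Whether neighbouring row numbers are neighbouring spots is not known, and the wave of 110.5 rows is the only evidence for it here. If they are, bright patches on the TAR array behind most of the 52 probes are argued against as well. With values floored at the 25th percentile and the running median removed, the 104 rows next to those 52 probes had a median difference of 0.038 on the log2 scale (95% bootstrap interval -0.02 to 0.107). This median includes dim neighbours and would hardly move if only a minority of the 52 probes lay in patches. The bootstrap drew rows singly and so ignored that rows flanking the same probe belong together. Only directly adjoining row numbers were examined, not rows a wave length away. Isolated bright spots on the TAR array and a true gain of signal in the resistant clone stay open. Without a second array or gene names, neither was tested.

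At the floor of the deposited values, 1270 probes were at 0.001 in the control and above it in TAR, and 965 were at 0.001 in TAR and above it in the control. Of these, 63 and 55 reached the array median in the other array, and 3 and 4 reached its 75th percentile. The highest such value was 297.6 units in TAR and 486.5 units in the control. Within the range of periods searched, the mean level of all probes, floor values included, had its strongest period at 2265 rows, or 24 cycles over the table. A strongest period always exists, and neither its size nor a permutation was computed, so a periodic variation is not established.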
